A study of Mus musculus with 24 samples.

How the data were processed

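RNA from NIH3T3 mouse fibroblasts was sequenced in 24 libraries: 16 from whole cells, with 4 replicates each of input and pulldown for a miR-29b mimic and a scrambled mimic, and 8 from nuclear and cytoplasmic fractions with 1 library each. Per the labels, libraries were made from 5 ng of RNA, except 6 ng for replicate 4 of the miR-29b input, with a kit primed by random hexamers and oligo-dT. Per the submitters' processing notes, STAR 2.3.0 and the mm10 build were used. The counting tool, its annotation version, its strand setting and the filter on listed genes are not given in the sources used here. The deposited tables hold a whole-number count per gene and library. The authors also deposited CPM values, which equal the count plus 1 divided by a library total that exceeds the listed counts; the listed counts were 48.9% to 87.3% of those totals. The authors' deposited score per gene and replicate is called PE in the file headers, and its formula was not recovered from the values. The authors' table also marks their calls and predicted sites, whose origin is read only from the column names. The nuclear table was identical to the cytoplasmic one (0 bytes differed), and both fractions were read from it.

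The whole-cell table had 14052 lines for 13534 genes, since 365 genes were repeated, and 518 repeat lines were dropped. Counts were tested with edgeR 4.0.16 in R 4.3.3, using filterByExpr, TMM factors and the quasi-likelihood test, in 1 model of group means over all 16 libraries. Of the genes, 12915 were tested and 619 fell under the filter. The common dispersion was 0.106. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of 5 comparisons, with a threshold of 0.05. Log2 CPM values used a prior count of 2. Of the genes tested, 12895 had a symbol, and 11758 symbols were matched in a gene table of GRCm38.p6, from which coordinates were taken.

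Named genes were, per comparison, the 8 highest and 8 lowest log2 changes among genes past the threshold, with a mean of at least 5 CPM in the higher group, an official symbol and no overlap between the libraries of the groups compared. Up to 3 members of each gene list with the smallest p and 12 fixed genes, of which 11 were tested and Eln was not, were added. Some genes that the rule names are not reported here. These rules, the 26 gene lists, the tests and all alternatives below except those said to be added later were set before the data were examined. Lists were tested with fry from limma 3.58.1, which asks whether the genes of a list move on balance one way and does not compare them with other genes, and with camera with a preset and with an estimated correlation. No list called by fry in the mimic-specific comparison kept its call with the estimated correlation. That correlation came from residuals that include the difference of replicate 4 from the others. With the preset correlation the reported targets, collagens, Bcl2 family and RISC genes passed (camera adjusted p = 6.53e-21, 0.00905, 0.0399 and 0.0399). The other lists called by fry did not (camera adjusted p = 0.0667 to 0.731). Histones and ribosomal protein mRNAs passed downward (camera adjusted p = 0.0109 and 0.0399). Site marks were compared by Fisher's exact test, two-sided, over protein-coding genes tested, with adjustment over 40 tests. They replace a planned search for seed sites, since no annotation with untranslated regions was used here; the planned control motifs were therefore not run.

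The fractions were described with log2 ratios with a prior count of 5, after TMM, over 11568 genes with at least 20 counts in all 8 libraries together. Medians of lists were set against 10000 random lists matched on expression.

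Same-numbered libraries were taken as paired where every correlation of their deviations from the group means was over 0.1. This held for both inputs (0.506 to 0.717) and for the miR-29b pulldown and its input (0.379 to 0.70), but not where the scrambled pulldown took part. Replicate 4 stood apart in the groups that passed, so replicates 1 to 3 share a deviation and can pass under any numbering. The rule therefore cannot establish pairs. Between inputs each replicate correlated best with its own number. Replicate 2 of the miR-29b input correlated best with replicate 3 of its pulldown. Counts of the blocked model had been seen when this was settled.

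Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter or a filter of 2 CPM in 4 libraries, the replicate number as a block, only the groups compared, a threshold of 2-fold, and leaving out each library. Subsets of replicates, the 10 libraries, the authors' library totals, another background for site marks, and the correlation of pulldown and input changes under the other scalings, tools, filters and models were added after the data were seen. In simulated counts with 4-fold changes, the pipeline recovered 78.8% in the mimic-specific comparison over 12809 genes, 100.0% between pulldowns over 12803 genes and 95.5% between inputs over 12806 genes. For 2-fold changes it recovered 4.48%, 35.8% and 38.8%. The simulated libraries were independent, with 1 mean per gene apart from the changes set. They held no replicate 4 that stands apart, no pairs and no difference between input and pulldown. Recovery in the real libraries may therefore differ.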

Results

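NIH3T3 cells, a line of mouse embryonic fibroblasts, were transfected with a mimic of miR-29b or with a scrambled control mimic. Both mimics carried 3-cyanovinylcarbazole, a nucleoside that can be crosslinked to the opposite strand by light, and per the labels were used at 10 nM. Medium was added after 24 h and the cells were harvested 8 h later. RNA was sequenced from the input and from the material recovered in the pulldown. MiR-29b is a microRNA whose reported targets include many collagens and other matrix genes. There were 16 whole-cell libraries in 4 groups of 4, namely miR-29b input, scrambled input, miR-29b pulldown and scrambled pulldown. A further 8 libraries came from cytoplasmic and nuclear fractions, with 1 library for each combination of fraction, mimic and pulldown or input. Nothing in the labels says that same-group libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical.

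The counts listed per whole-cell library ranged from 7409157 in replicate 1 of the scrambled pulldown to 55153996 in replicate 4 of the miR-29b input. All whole-cell libraries detected between 12579 and 13518 genes. The headers of the authors' table call replicates 1 to 3 lysed and replicate 4 intact, so that the intact set has 1 library per group and no test of its own. The first 3 principal components held 46.0%, 19% and 17.8% of the variance. On the third, replicate 4 lay at 76.2 in the miR-29b input, 72.9 in the scrambled input and 65.0 in the miR-29b pulldown, but at −14.8 in the scrambled pulldown, next to replicates 2 and 3 of its group at −15.4 and −18.5. In the miR-29b pulldown, replicate 3 lay between replicates 1 and 2 in 547 of the 550 genes that differed over 2-fold between these. Values from replicates 1 to 3 and from 10 libraries, leaving out replicate 3 of every group, replicate 4 of the miR-29b input and replicate 4 of the scrambled pulldown, therefore stand beside the pooled counts. Both sets were chosen after the data were seen.

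The comparison that the design implies for targets sets the pulldown over input ratio with miR-29b against the same ratio with the scrambled mimic. Genes of the extracellular matrix and of apoptosis control were among those recovered more with miR-29b. Mcl1 (ENSMUSG00000038612; chromosome 3, 95656944 to 95663179, GRCm38), an anti-apoptotic member of the Bcl2 family, was 18.2-fold more enriched (log2 change 4.19 ± 0.56 SE, n = 4 per group, edgeR adjusted p = 6.58e-05). Its level was 1795 ± 359 CPM (counts scaled to library size; SD, n = 4) in the miR-29b pulldown and 54.4 ± 4.94 CPM in the scrambled pulldown, against 139 ± 116 CPM and 76.8 ± 18.6 CPM in the inputs. Without replicate 4 of the miR-29b input, which held 313.81 CPM of Mcl1, the log2 change of Mcl1 was 5.02 (edgeR adjusted p = 1.46e-08). Of the genes named by rule whose pulldown libraries did not overlap between mimics, Efna2, an ephrin ligand, changed most, at 31.03-fold (log2 4.96 ± 0.46 SE). Snx24, a sorting nexin, followed at 21.4-fold, then Slc40a1, the iron exporter ferroportin, at 21.3-fold and Cd276, an immune checkpoint protein, at 19.1-fold. Hbp1, a transcriptional repressor, Klf4, a transcription factor, and C1qtnf6, a secreted protein, were 17.4-fold, 17.1-fold and 16.5-fold higher. Leaving out the same input library moved Slc40a1 to 5.07 and Klf4 to 4.94 on the log2 scale (edgeR adjusted p = 4.57e-08 and 2.21e-07). In all 8 of these genes the adjusted p of edgeR's quasi-likelihood test lay at or under 0.000161 and the 4 miR-29b pulldown libraries lay above the 4 scrambled ones.

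Among 12915 genes tested, 2192 were higher and 1190 lower at an adjusted p under 0.05 (edgeR), of which 1801 and 748 changed at least 2-fold. Upper-quartile scaling turned this split to 1662 higher and 2400 lower, as it moved the median of all genes from −0.10 to −0.39, and the authors' library totals gave 2466 and 283 with a median of 0.21. Replicates 1 to 3 alone gave 3127 higher and 2457 lower, replicates 1, 2 and 4 gave 1004 and 233, and the 10 libraries gave 1273 and 180. Leaving out replicate 3 of the scrambled input alone left 783 lower.

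Of the reported miR-29 targets, a list fixed before the data were examined, 51 of 78 measured genes rose, none fell and 27 did not pass (56 rose when adjusted over the list alone). The median log2 change was 2.13 (fry adjusted p = 0.000534; adjusted p = 0.48 with an estimated correlation). Sparc, a matrix glycoprotein, rose 5.10-fold (log2 2.35 ± 0.21 SE, edgeR adjusted p = 2.57e-06), and Kctd5 rose by 2.91 ± 0.29 on the log2 scale (edgeR adjusted p = 6.24e-06). Dnmt3a, a de novo DNA methyltransferase, rose 7.32-fold (edgeR adjusted p = 0.00542) and Tdg, a thymine DNA glycosylase, 6.55-fold (edgeR adjusted p = 0.00144). The dioxygenase gene Tet3 had a log2 value of 2.59 ± 1.08 (edgeR adjusted p = 0.0926), with 1549 ± 718 CPM in the miR-29b pulldown and 112.7 ± 174 CPM in its input. Fbn1, which encodes fibrillin, and Dnmt3b had log2 values of 1.40 ± 0.77 and 1.70 ± 0.78 (edgeR adjusted p = 0.204 and 0.129). Without replicate 4 of the miR-29b input, Tet3, Fbn1 and Dnmt3b reached 4.80, 2.86 and 2.90 (edgeR adjusted p = 1.36e-05, 4.66e-05 and 0.00208), and Dnmt3a and Tdg had log2 changes of 3.86 and 3.59 (edgeR adjusted p = 1.37e-05 and 1.31e-07).

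Collagens were the matrix group that moved most, with 11 of 22 measured genes higher and 1 lower (12 and 1 when adjusted over the list alone), a median log2 change of 1.72 and a fry adjusted p of 0.00469 (adjusted p = 0.885 with an estimated correlation). Of these 22 genes, 12 are also on the list of reported targets. Col1a1 (ENSMUSG00000001506; chromosome 11, 94936224 to 94953042, GRCm38) rose 6.69-fold after correction for input (edgeR adjusted p = 0.00878). Its level was 377 ± 86.2 CPM in the scrambled pulldown and 4875 ± 1653 CPM in the miR-29b pulldown, 12.9-fold higher between the pulldowns alone (edgeR adjusted p = 4.64e-05). Col1a2, Col3a1 and Col4a1 rose 5.56-fold, 5.65-fold and 8.29-fold (edgeR adjusted p = 0.000131, 0.00577 and 0.000321). Without replicate 4 of the miR-29b input the log2 changes of Col1a1 and Col3a1 were 3.93 and 3.41 (edgeR adjusted p = 1e-06 and 2.33e-06). With replicates 1, 2 and 4 the calls of Col1a1, Col3a1 and Dnmt3a ended (edgeR adjusted p = 0.0922, 0.0776 and 0.0778), as did that of the collagen list (fry adjusted p = 0.0995). The elastic fibre and cross-linking list split, with 5 higher and 7 lower of 25 (5 and 7 when adjusted over the list alone; fry adjusted p = 0.979). Lox, the lysyl oxidase, rose by 3.33 ± 0.45 and Emilin1 fell by 1.47 ± 0.19 on the log2 scale. Other matrix glycoproteins and proteases had 4 higher and 3 lower of 22 (4 and 3 when adjusted over the list alone; fry adjusted p = 0.979), with the perlecan gene Hspg2 at −1.79 ± 0.33, which did not pass with the 10 libraries (edgeR adjusted p = 0.0695).

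**Figure D1:**
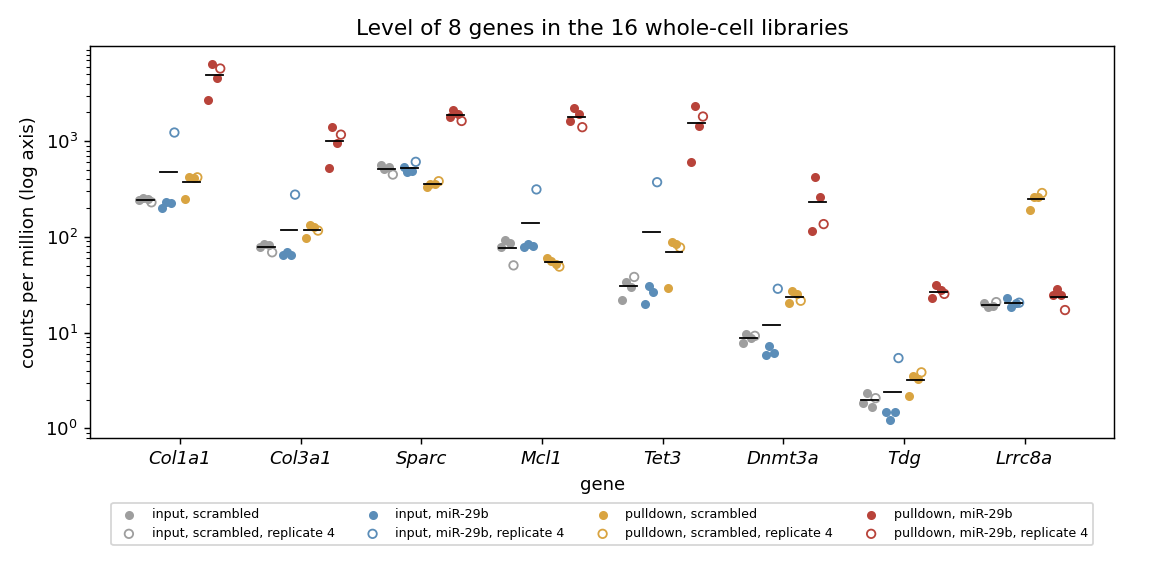
Level of 8 genes in each of the 16 whole-cell libraries, in CPM on a log axis, with a black bar at each group's mean and open circles for replicate 4. For Col1a1, Col3a1, Mcl1, Tet3, Dnmt3a and Tdg the open circle of the miR-29b input lies above the other inputs, and for Lrrc8a the scrambled pulldown lies at 249 ± 40.95 CPM (SD, n = 4) against 23.9 ± 4.79 CPM with miR-29b.

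In the Bcl2 family 7 of 14 measured genes rose and 1 fell (7 and 1 when adjusted over the list alone; median log2 1.04, fry adjusted p = 0.00983; adjusted p = 0.885 with an estimated correlation). Beside Mcl1 these included the pro-apoptotic effectors Bak1, at 2.88 ± 0.34 on the log2 scale, and Bax, at 1.58 ± 0.29. Of 22 p53 targets 10 rose and 2 fell (11 and 4 when adjusted over the list alone; fry adjusted p = 0.00347; adjusted p = 0.885 with an estimated correlation). The cell cycle inhibitor Cdkn1a was among them at 2.58 ± 0.42, as was the death receptor Fas at 1.68 ± 0.22. Of 28 RISC and miRNA processing genes 8 rose and 2 fell (9 and 2 when adjusted over the list alone; fry adjusted p = 0.0249; adjusted p = 0.885 with an estimated correlation), including the deadenylase subunits Cnot6l at 2.48 ± 0.30 and Cnot7 at 1.71 ± 0.24. TGF-beta and myofibroblast genes went both ways, with 10 higher and 4 lower of 28 (10 and 6 when adjusted over the list alone; fry adjusted p = 0.00469; adjusted p = 0.885 with an estimated correlation). The tropomyosin genes Tpm1 and Tpm2 lay at 2.14 ± 0.20 and −1.76 ± 0.18. With replicates 1, 2 and 4, the fry adjusted p was 0.109 for the Bcl2 family, 0.0707 for p53 targets, 0.173 for RISC genes and 0.0676 for TGF-beta genes. With the 10 libraries it was 0.0884 for the Bcl2 family and for TGF-beta genes. With upper-quartile scaling these were 0.0781, 0.0821, 0.262 and 0.951. The RISC list also lost its call with the stricter filter of 2 CPM in 4 libraries (fry adjusted p = 0.0581) and without miR-29b input replicate 1, 2 or 3, scrambled input replicate 4, miR-29b pulldown replicate 2 or scrambled pulldown replicate 1 (fry adjusted p up to 0.0781).

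Of the genes named by rule, Lrrc8a was recovered least with miR-29b relative to the scrambled mimic (ENSMUSG00000007476; chromosome 2, 30237769 to 30263790, GRCm38). This gene of a volume-regulated anion channel subunit was 10.96-fold lower (log2 −3.46 ± 0.24 SE, edgeR adjusted p = 1.15e-06). Its inputs were level at 20.6 ± 1.83 and 19.6 ± 1.14 CPM. Edf1, a transcriptional coactivator, was 7.90-fold lower and Cpt1c, a brain-type carnitine palmitoyltransferase, 7.49-fold lower (edgeR adjusted p = 1.15e-05 and 3.38e-05). Hist2h3b, Lars2, Mypop and Scand1 had log2 changes of −2.80, −2.73, −2.68 and −2.65. Hist2h3b belongs to a multigene family whose copies share reads, so its count is uncertain. With the 10 libraries Hist2h3b and Scand1 no longer passed (edgeR adjusted p = 0.663 and 0.159), nor did Hist2h3b with the authors' totals (edgeR adjusted p = 0.0626). Hist2h3b passed without input replicate 1 of miR-29b, input replicate 4 or pulldown replicate 1 of the scrambled mimic, or pulldown replicate 4 of miR-29b, and lost its call without any other library (edgeR adjusted p up to 0.112). Its log2 change was −1.94 without replicate 4 of the miR-29b input and −3.73 without replicate 4 of the miR-29b pulldown.

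Of 23 genes of cholesterol synthesis and uptake 6 rose and 1 fell (6 and 1 when adjusted over the list alone), among them Pmvk at 2.12 ± 0.30, Insig1 at 2.84 ± 0.50 and Sc5d at 1.03 ± 0.19. The median of that list was −0.01 and its mean 0.36, while fry gave a direction upward (adjusted p = 0.0196; adjusted p = 0.927 with an estimated correlation), which upper-quartile scaling turned (fry adjusted p = 0.536) and which did not pass with replicates 1, 2 and 4 (fry adjusted p = 0.109). Sc5d did not pass with the 10 libraries (edgeR adjusted p = 0.0775), and Insig1 was at 3.56 without replicate 4 of the miR-29b input (edgeR adjusted p = 2.9e-07). Nuclear-retained RNAs had 1 of 5 measured genes lower, Neat1 at −1.04 ± 0.35 (3 lower when adjusted over the list alone; fry adjusted p = 0.0491; adjusted p = 0.885 with an estimated correlation). Neat1 lost its call without miR-29b input replicate 2, 3 or 4, scrambled input replicate 2, or replicate 2, 3 or 4 of either pulldown (edgeR adjusted p up to 0.0712). Neat1 did not pass with the 10 libraries (edgeR adjusted p = 0.299), nor did its list, with these or with replicates 1, 2 and 4 (fry adjusted p = 0.283 and 0.184), and leaving out any single library but miR-29b pulldown replicate 4 ended the call of the list (fry adjusted p up to 0.138). So did RLE factors, the stricter filter and the authors' totals (fry adjusted p = 0.0595, 0.0674 and 0.251), the last also for Neat1 (edgeR adjusted p = 0.28). Replication-dependent histones had 2 of 51 lower and none higher (1 lower when adjusted over the list alone; fry adjusted p = 0.381). Of 74 ribosomal protein mRNAs 1 rose and 5 fell (1 and 4 when adjusted over the list alone; fry adjusted p = 0.476). DNA methylation enzymes had 2 higher and 1 lower of 18 (2 and 1 when adjusted over the list alone; fry adjusted p = 0.309, and 0.00414 without replicate 4 of the miR-29b input), the cell cycle list 4 and 1 of 38 (3 and 0 when adjusted over the list alone; fry adjusted p = 0.979) and the unfolded protein response 1 and 4 of 23 (1 and 1 when adjusted over the list alone; fry adjusted p = 0.476). Of 33 interferon genes 1 passed over all libraries, Rsad2 at 5.60 ± 1.46 (0 when adjusted over the list alone; fry adjusted p = 0.979). In the miR-29b pulldown Rsad2 stood at 874 to 1219 CPM in replicates 1 to 3 and at 19.6 CPM in replicate 4, with inputs of 4.41 and 1.635 CPM in replicate 4. Replicate 4 of the scrambled pulldown held 31.95 CPM, next to 31.4 and 34.8 CPM in replicates 2 and 3 of its group, as on the third principal component. Rsad2 did not pass with replicates 1, 2 and 4 or with the 10 libraries (edgeR adjusted p = 0.104 and 0.213). Of 12 snoRNA hosts 1 rose, Snhg6 at 3.44 ± 0.47, or 4.12 without replicate 4 of the miR-29b input (1 when adjusted over the list alone; fry adjusted p = 0.839). Within replicates 1 to 3 alone the lists of histones, small structural RNAs, interferon genes, DNA methylation enzymes and the unfolded protein response passed (fry adjusted p = 0.0368, 0.0112, 0.0171, 0.0299 and 0.00496). None of 13 mitochondrial mRNAs and none of 9 small structural RNAs passed (fry adjusted p = 0.623 and 0.159).

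Few markers of other cell types were measured. Of 5 muscle markers 1 fell, Acta1 at −2.99 ± 0.36 (1 when adjusted over the list alone; fry adjusted p = 0.00093; adjusted p = 0.48 with an estimated correlation). Of 14 fibroblast markers 6 rose and 1 fell (6 and 1 when adjusted over the list alone; fry adjusted p = 0.0242; adjusted p = 0.885 with an estimated correlation), and 4 of them are also reported targets. Neither of 2 epithelial markers passed alone, although their list did (fry adjusted p = 0.00181; adjusted p = 0.885 with an estimated correlation). The calls of the muscle and fibroblast lists ended with the 10 libraries (fry adjusted p = 0.0697 and 0.0884), and those of the fibroblast and epithelial lists with replicates 1, 2 and 4 (fry adjusted p = 0.173 and 0.0676). Upper-quartile scaling gave the fibroblast list a fry adjusted p of 0.427. Of 5 neural markers 2 rose, among them Stmn2 at 1.13 ± 0.17 (2 when adjusted over the list alone; fry adjusted p = 0.0973). The neural list passed without scrambled input replicate 4 or scrambled pulldown replicate 1 (fry adjusted p = 0.0408 and 0.00291). Of 8 adipocyte markers 1 fell, Cebpa at −1.85 ± 0.51 (1 when adjusted over the list alone; fry adjusted p = 0.816), which did not pass with the 10 libraries or the authors' totals (edgeR adjusted p = 0.088 and 0.0679). No gene passed among 3 endothelial and 3 leukocyte markers (fry adjusted p = 0.555 for both). The median and the mean of the leukocyte and adipocyte lists differed in sign, and the neural list had a median of −0.51 and a mean of −0.06 although fry's direction was upward.

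The authors' table marks genes with a predicted miR-29 site, which its column names attribute to TargetScan. Among the protein-coding genes tested, 327 of 2125 that were higher in this comparison carried such a mark (15.4%), against 173 of 8283 that were not called (2.09%). The odds ratio was 8.52 (95% interval 7.02 to 10.4; Fisher's exact test, two-sided, adjusted p = 1.55e-110 over 40 tests). With the 10 libraries it was 14.5. For marks of an 8mer site, the longest canonical seed match, the odds ratio was 11.3. Among lower genes 7 of 1093 carried a mark (odds ratio 0.302, adjusted p = 0.00106, Fisher's exact test). Marked genes had a median log2 change of 1.77 and unmarked genes of −0.09. In the scrambled pulldown against its input, which holds no miR-29b mimic, 111 of 2173 higher genes were marked against 343 of 7148 not called (odds ratio 1.07, adjusted p = 0.759, Fisher's exact test). Lower genes carried fewer marks there too, 53 of 2180 (odds ratio 0.494, adjusted p = 1.7e-06, Fisher's exact test).

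Recovered RNA was next compared directly between the pulldowns of both mimics, without the inputs. Wisp1, a matricellular signalling protein, was 47.2-fold higher with miR-29b (log2 5.56 ± 0.92 SE, edgeR adjusted p = 0.000144), followed by Nrep at 41.9-fold, Ppp1r3d, a glycogen-targeting phosphatase subunit, at 37.4-fold, and Zfp322a at 34.1-fold. Mcl1 was 33.0-fold higher and Eda2r 31.5-fold. Hba-a1 was 31.7-fold higher, but shares reads with a near-identical copy and is uncertain; without miR-29b pulldown replicate 4 its log2 change was 4.15 (edgeR adjusted p = 0.00446). Lrrc8a was 10.4-fold lower (log2 −3.39 ± 0.18 SE, edgeR adjusted p = 9.69e-09). Endov and Ppp1r15a, a regulatory subunit of the phosphatase acting on eIF2 alpha, were 6.67-fold and 6.09-fold lower. Of the reported targets 71 of 78 rose and none fell (72 and 2 when adjusted over the list alone; fry adjusted p = 1.12e-05; adjusted p = 0.436 with an estimated correlation). Of the collagens 13 of 22 rose and 1 fell (13 and 1 when adjusted over the list alone; fry adjusted p = 0.000126; adjusted p = 0.657 with an estimated correlation). Tet3, Fbn1 and Dnmt3b passed here, at 21.99-fold, 4.98-fold and 5.91-fold (edgeR adjusted p = 0.000568, 0.00325 and 0.00115). In total 3163 genes were higher and 2703 lower (edgeR), of which 2191 and 1311 at least 2-fold. Upper-quartile scaling gave 2462 and 4333 and the authors' totals 3795 and 1089, so the split depends on the scaling. Replicates 1 to 3 gave 3780 and 3784, replicates 1, 2 and 4 gave 2453 and 1463, and the 10 libraries 2086 and 955.

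The inputs show RNA levels after the mimic, and few differences were called between them. Of 12915 genes 7 were higher with miR-29b and none was lower (edgeR). An unadjusted p under 0.05 was reached by 604, less than the share of 0.05 awaited where no gene differs. The model pooled the lysed and intact sets, so their difference entered the spread and can hide differences between mimics. The shortage of small p therefore does not show that none exist. DESeq2 called 32 higher and 14 lower. Srpr, a subunit of the signal recognition particle receptor, rose 2.90-fold (log2 1.54 ± 0.23 SE, edgeR adjusted p = 0.0152) and Dhcr7, the last enzyme of cholesterol synthesis, 2.15-fold (edgeR adjusted p = 0.0152). Dynlt3, D1Ertd622e, Zmpste24 and Adh7 rose 2.01-fold, 1.94-fold, 1.91-fold and 1.79-fold. The seventh gene, Dok4, rose by 1.67 ± 0.21 (edgeR adjusted p = 0.00549) and fell outside the rule for named genes, so it was named after its value was seen. None of the 7 carried a site mark. No reported target passed (0 of 78, and 0 when adjusted over the list alone; median log2 0.37, fry adjusted p = 0.856), nor did any collagen (0 of 22, and 0 when adjusted over the list alone; fry adjusted p = 0.474). Of the cholesterol genes only Dhcr7 passed (1 of 23, and 1 when adjusted over the list alone; fry adjusted p = 0.0237; adjusted p = 0.0588 with an estimated correlation). With the replicate number as a block, which treats these samples as paired, the list had a fry adjusted p of 0.0582. It was 0.0515 without miR-29b pulldown replicate 2, 0.28 with the 10 libraries, 0.191 with only the groups compared and 0.952 with the authors' totals (fry). With replicates 1, 2 and 4 and with replicates 1 and 2 it was 0.222 and 0.633 (fry).

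The input result changed with the libraries used. Replicates 1 to 3 gave 82 genes higher and 95 lower, whereas replicates 1, 2 and 4, replicates 1 and 2, and the 10 libraries each gave 0 and 0 (edgeR). With only the groups compared, 0 genes were higher and 0 lower (edgeR), and none of the 7 passed, from Srpr, Dynlt3, Adh7 and Dok4 (edgeR adjusted p = 0.0998) to Dhcr7 and Zmpste24 (edgeR adjusted p = 0.164). The authors' library totals left 1, Dok4 (edgeR adjusted p = 0.031). With the replicate number as a block, which treats these samples as paired, 10 genes were higher and 1 lower, and the call of Zmpste24 ended. Srpr lost its call without any one of replicates 1 to 3 of either input (edgeR adjusted p = 0.0555 to 0.0927), as did D1Ertd622e, and Dhcr7 without any of these but scrambled input replicate 1. Dok4 lost its call without miR-29b input replicate 1 or scrambled input replicate 2 or 3 (edgeR adjusted p up to 0.0766). Adh7 lost its call without any one of replicates 1 to 3 of either input and without miR-29b input replicate 4 (edgeR adjusted p up to 0.202). Zmpste24 lost its call without any single library other than miR-29b input replicate 4, miR-29b pulldown replicate 2 or 4 and scrambled pulldown replicate 1 (edgeR adjusted p up to 0.136). The number higher was 1 without miR-29b input replicate 1 and without scrambled input replicate 2 or 3, 2 without miR-29b input replicate 2 or 3, and 3 without scrambled input replicate 1. It was 11, with 1 lower, without miR-29b pulldown replicate 4, and leaving out scrambled input replicate 4 or scrambled pulldown replicate 1 gave 2 and 1 lower. In simulated counts with known changes but no lysed or intact sets, this comparison recovered 38.8% of 2-fold and 95.5% of 4-fold changes. In replicate 4 of the miR-29b input, Col1a1 stood at 1233 CPM against 202 to 229 CPM in replicates 1 to 3, and Tet3 at 373 CPM against 20.1 to 30.6 CPM. Within replicates 1 to 3 the log2 changes of Col1a1, Col3a1, Tet3 and Mcl1 were −0.21, −0.32, −0.15 and −0.09.

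Across genes, the change in the pulldown and the change in the input had a Pearson correlation of 0.358 and a Spearman correlation of 0.316, where genes are not independent replicates. All 7 genes higher in the input were among the 3163 higher in the pulldown. If both calls were independent, 1.71 would be awaited (Fisher's exact test, two-sided, p = 5.26e-05). The calls are not independent, since pulldown levels were not corrected for input and numbers may pair the miR-29b pulldown with its input. The overlap therefore cannot show added recovery. After correction for input, Dynlt3, Zmpste24, D1Ertd622e and Dhcr7 did not pass (edgeR adjusted p = 0.181 to 0.915). Their log2 changes were −0.03, −0.42, 0.14 and −0.27. Srpr, Dok4 and Adh7 passed at log2 1.59, 0.94 and 1.13 (edgeR adjusted p at or under 0.0261). The correlation was 0.03 with replicates 1 to 3 and −0.03 with the 10 libraries, so that it did not hold within the lysed set. Without replicate 4 of the miR-29b input it was 0.02.

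With miR-29b, pulldown against its own input had Bmf, a pro-apoptotic Bcl2 modifying factor, 43.9-fold higher (log2 5.46 ± 0.76 SE, edgeR adjusted p = 2.65e-05). Its level in that pulldown was 29.12 to 142.4 CPM in replicates 1 to 3, but 5.25 CPM in replicate 4, whose input held 1.54 CPM. The scrambled pulldown held 3.41 to 8.57 CPM of Bmf, against 0.648 to 2.15 CPM in its input. Frat2, a Wnt pathway regulator, Zbtb5 and Dnmt3a were 23.4-fold, 23.2-fold and 19.4-fold higher, and Acvr2a, an activin receptor, was 17.9-fold higher. Without replicate 4 of the miR-29b input, the log2 changes of Frat2, Zbtb5, Dnmt3a and Acvr2a were 5.55, 5.23, 5.23 and 5.24, and without replicate 2 of the miR-29b pulldown that of Bmf was 4.75 (edgeR adjusted p at or under 6.93e-05 in each). Among the lowest were Tgfb1, the growth factor TGF-beta 1, at 4.78-fold lower, the transcription factor Cebpb at 4.75-fold lower and Pabpc1, a poly(A)-binding protein, at 4.14-fold lower. Lars2 was 4.19-fold lower. Of the reported targets 71 rose and 1 fell of 78 (71 and 1 when adjusted over the list alone; fry adjusted p = 1.6e-06; adjusted p = 0.533 with an estimated correlation), and 15 of 22 collagens rose and 1 fell (15 and 1 when adjusted over the list alone; fry adjusted p = 2.99e-06; adjusted p = 0.533 with an estimated correlation). Of the ribosomal protein mRNAs 43 of 74 fell and 1 rose (45 and 1 when adjusted over the list alone; fry adjusted p = 0.00983; adjusted p = 0.969 with an estimated correlation). This list did not pass with only the groups compared, with replicates 1, 2 and 4, with replicates 1 and 2, or with the 10 libraries (fry adjusted p = 0.0768, 0.0721, 0.0771 and 0.2). In total 3672 genes were higher and 2991 lower (edgeR). Upper-quartile scaling gave 2925 and 4208 and the authors' totals 4242 and 1570. Replicates 1 to 3 gave 4371 and 3973, replicates 1, 2 and 4 gave 2720 and 1808, and the 10 libraries 2679 and 1877.

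With the scrambled mimic, the pulldown against its input measures what is recovered without a miR-29b sequence. Noncoding RNAs of the nucleus and small RNAs were among the highest. Malat1, a nuclear-retained long noncoding RNA, was 27.8-fold higher (log2 4.80 ± 0.61 SE, edgeR adjusted p = 3.77e-05), and Neat1, the scaffold RNA of paraspeckles, 13.4-fold higher (edgeR adjusted p = 1.01e-06). Of 5 nuclear-retained RNAs 4 rose and none fell (4 when adjusted over the list alone; fry adjusted p = 5.47e-05; adjusted p = 0.527 with an estimated correlation). Small Cajal body RNAs Scarna13 and Scarna2 were 31.5-fold and 24.2-fold higher. In replicates 1 to 3 their scrambled inputs held only 0 to 0.115 and 0.0764 to 0.137 CPM, so these sizes are uncertain. Of 9 small structural RNAs 5 rose (5 when adjusted over the list alone, fry adjusted p = 0.0275, adjusted p = 0.999 with an estimated correlation). Dnm3os, at 103.2-fold, is antisense to Dnm3, and since the strand of counting is not stated its reads cannot be told from those of Dnm3. Rnu3a and Snora73b, at 29.6-fold and 47.9-fold, have related copies and are uncertain. Scrambled input replicates 1 to 3 held at most 0.258, 0.228 and 0.191 CPM of Dnm3os, Rnu3a and Snora73b. Ttn, which encodes the muscle protein titin, had a log2 change of 5.84 ± 1.24 (edgeR adjusted p = 0.00188), with 12.5 ± 18.6 CPM in the pulldown, and of 3.94 without replicate 1 of the scrambled pulldown (edgeR adjusted p = 0.00629). Of 51 histone genes 13 rose (9 when adjusted over the list alone; fry adjusted p = 0.164), and 24 of 74 ribosomal protein mRNAs fell while 1 rose (24 and 1 when adjusted over the list alone; fry adjusted p = 0.153). Collagens had 7 of 22 higher (7 when adjusted over the list alone; fry adjusted p = 0.0145; adjusted p = 0.999 with an estimated correlation), with Col12a1 at 2.41 ± 0.44. The collagen list lost its call without scrambled input replicate 4 (fry adjusted p = 0.0798), and the small structural RNAs theirs with the stricter filter (fry adjusted p = 0.0538) and without scrambled input replicate 1, 2 or 3 or scrambled pulldown replicate 1 (fry adjusted p up to 0.115). With replicates 1, 2 and 4, with replicates 1 and 2, and with the 10 libraries neither passed (fry adjusted p = 0.105, 0.117 and 0.0658 for collagens, and 0.189, 0.0663 and 0.137 for small structural RNAs). Without replicate 4 of the scrambled input, the log2 changes of Dnm3os, Snora73b, Scarna13, Rnu3a and Scarna2 were 7.75, 7.07, 6.49, 6.23 and 6.09, and without replicate 1 of the scrambled pulldown those of Snora73b and Rnu3a were 4.75 and 3.59. Scarna13 did not pass with replicates 1, 2 and 4 (edgeR adjusted p = 0.0503). Among the lowest were Tm2d1, Spg21 and Med30 at 4.12-fold, 3.79-fold and 3.54-fold lower, and the transcription factor Twist1 was 3.34-fold lower. In total 2392 genes were higher and 2246 lower (edgeR), of which 1400 and 741 at least 2-fold. Replicates 1 to 3 gave 3552 and 3386, replicates 1, 2 and 4 gave 1096 and 994, and the 10 libraries 709 and 442.

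**Figure D2:**
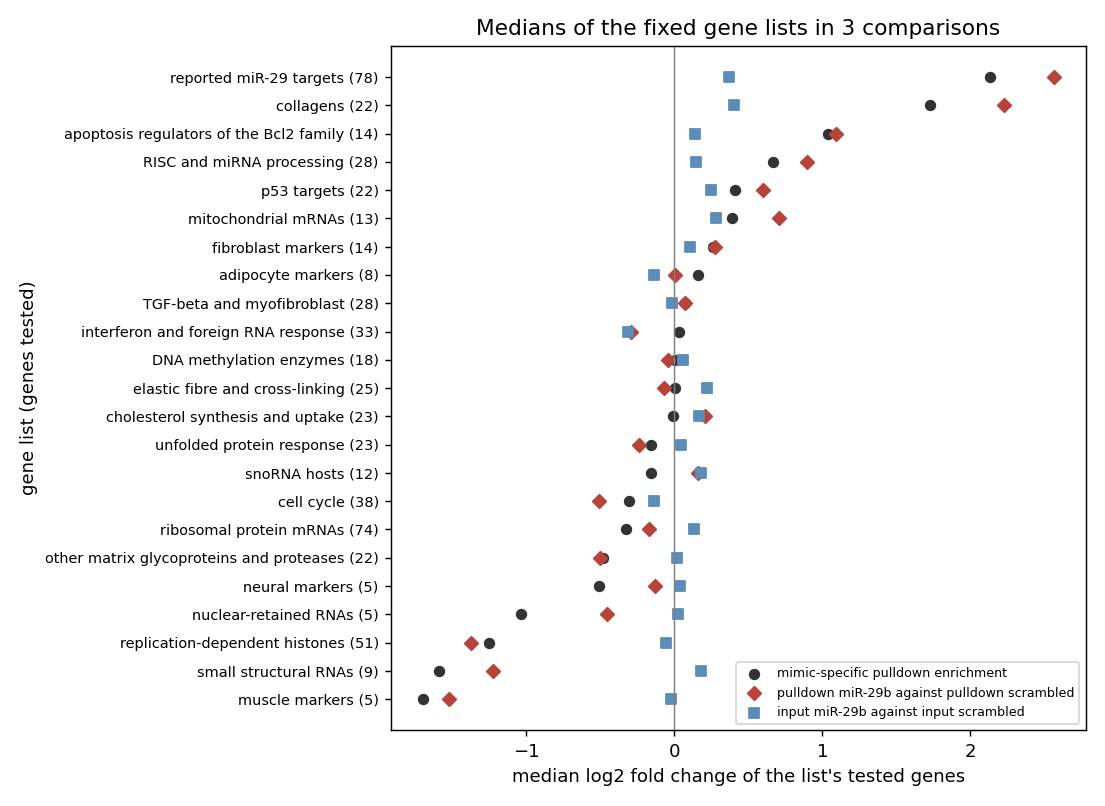
Median log2 fold change of each fixed gene list with at least 5 measured genes, in 3 comparisons (black circles, mimic-specific enrichment; red diamonds, pulldown against pulldown; blue squares, input against input), with the number of genes tested in brackets. The reported miR-29 targets lie at 2.13, 2.56 and 0.37, the highest of the lists in both pulldown comparisons.

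The fractionated cells have 1 library per condition and no replicate check, so list medians were set against 10000 random lists of matched size and expression, as a description of these libraries. In the cytoplasm, the median log2 enrichment of 75 reported targets was 0.57, above 99.8% of random lists, and that of 140 genes with an 8mer mark 0.98, with a median of 0.83 between pulldowns and of −0.10 between inputs, below all random lists. In the nucleus the same lists lay at 0.46 and 0.41, above all random lists. Between nuclear inputs the 8mer list had a median of 0.05, above 96.54% of random lists. The reported targets lay at −0.02 between cytoplasmic and 0.03 between nuclear inputs, above 30.95% and 81.04% of random lists. Mcl1 had a log2 enrichment of 2.77 in the cytoplasm and 1.54 in the nucleus, and Sparc of 2.64 and 1.28, whereas Col4a1 had 0.30 and 2.40. Efna2 lay at 2.62 in the cytoplasm and −0.97 in the nucleus, where its libraries held 0.692 to 2.59 CPM. Dnmt3a lay at −0.04 and 0.23. The 18 collagens had medians of 0.36 in the cytoplasm, above 58.2% of random lists, and of 0.73 in the nucleus, above all of them. Lrrc8a stood at 9.32 CPM in the cytoplasmic miR-29b pulldown and at 260.4 CPM in the scrambled one. Listed counts ranged from 5320421 to 20142591 per library, with 11568 genes kept.

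The authors' deposited table gives a score per gene and replicate and calls genes from it. It lists 683 genes past the score in all lysed replicates, 979 in the intact one and 567 as positive hits, and a score over 4 returned the lysed and the intact calls with 0 differing genes. All 567 hits carried both of these calls. They were all higher in the comparison of both pulldowns and 497 in the comparison corrected for input. The hits were chosen on these same libraries and are not independent evidence of direction. Of the genes higher in the latter comparison, 1695 were not positive hits.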

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

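Of the tests in this part, those of the splits of the samples were set beforehand, and all others were chosen only after the result was seen. In groups of 4 libraries, a library was singled out where its gap to the nearest other exceeded the critical share of the group's range in Dixon's test (95%). This was run on 4 measures per library and on the levels of 14 genes. Chance singles out about 1 in 20 groups, and here 21 of 72 were. Replicate 4 of the miR-29b input stood apart in Col1a1 (1233.4 CPM), Col1a2 (995.99), Col3a1 (276.79), Fbn1 (28.212), Dnmt3a (28.755), Dnmt3b (1.9441), Tet3 (373.15), Tdg (5.4254), Mcl1 (313.81) and Malat1 (367.5 CPM), above replicates 1 to 3 in each. Replicate 4 of the scrambled input stood apart in Col1a2 (320.02 CPM), Col4a1 (110.06 CPM) and Malat1 (289.05 CPM). Replicate 4 of the miR-29b pulldown stood apart in Col4a1 (1313.8 CPM) and in the number of genes with a count, 12579 against 13449 to 13516. Replicate 1 of the scrambled pulldown stood apart in Col1a1 (248.18 CPM), Col4a1 (352.63 CPM), Malat1 (6418.9 CPM), Srpr (25.227 CPM) and the share of its 10 highest genes, 53.2% against 47.59% to 48.45%. In replicate 1 of the scrambled input, listed counts were 77.38% of the authors' total, against 75% to 75.19%.

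In 10 of those 14 genes the log2 ratio of miR-29b to scrambled input had 1 sign in replicate 4, the intact set, and the opposite sign in replicates 1 to 3; these differences were not tested. In replicate 4 the ratios were 2.423 for Col1a1, 2.002 for Col3a1, 1.576 for Col4a1, 2.082 for Fbn1, 0.4417 for Sparc, 1.636 for Dnmt3a, 3.289 for Tet3, 1.392 for Tdg, −0.02109 for Lrrc8a and 0.3464 for Malat1. The others of the 14 were Col1a2, Dnmt3b, Mcl1 and Srpr. Over a wider set, 34 of 69 named genes with a count in every input had such opposite signs.

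RNAs recovered with miR-29b stood above the scrambled input in replicate 4 of the miR-29b input. Genes without a site mark showed 1.021 times the share of marked genes. Since all of them were chosen as recovered in the miR-29b pulldown, unmarked genes may be bound by the mimic too. The marks therefore cannot decide whether the mimic raised its target RNAs in these cells. The excess in the input was 0.193 of the excess in the pulldown for 232 genes without a mark and 0.189 for 145 with one, against −0.01 to −0.00398 in replicates 1 to 3. The interquartile range in replicate 4 was narrow, at 0.182 to 0.202 without a mark and 0.177 to 0.197 with one. Admixed pulldown material would give such a near-constant share over genes, but it was seen in 1 library only. RNA or reads of the miR-29b pulldown in this input library are a candidate source (0.1931), and where they would have entered stays open.

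Replicate 4 of the scrambled pulldown did not part from replicates 1 to 3 where the other replicate 4 libraries did. Over 201 genes that part the inputs over 4-fold, its median log2 difference was 0.18, against 3.35 and 2.99 in the inputs and 3.20 in the miR-29b pulldown. A library made or labelled from the lysed set is a candidate explanation (0.1827). A scrambled pulldown that recovers the same RNA after both procedures cannot be told apart from it by the difference from its own input (−2.175), which both would give. A fit of this library from replicate 3 of its group left a residual of 2.97, relative to counting noise. Replicate 3 fitted from replicate 2 there left 2.995. In the other groups, replicate 4 fitted from replicate 3 left 59.53 to 124.7. The fit shows how near this library lay to the lysed set, not how that came about. No other biological explanation was tested.

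Replicate 3 lay between replicates 1 and 2 in 60.0%, 94.6%, 99.5% and 89.8% of the genes that differed over 2-fold between these, in miR-29b input, scrambled input, miR-29b pulldown and scrambled pulldown. The lowest share (60.0%, over 25 genes) left both a mixture of libraries 1 and 2 and an independent sample open, so that they cannot be told apart over all groups by this test. A further test for the miR-29b pulldown was chosen after that one left it open. There a fit of replicate 3 from replicates 1 and 2 left 0.0393 of the residual between these, against 0.303 and 0.330 from either alone. A mixture would give this, but an independent sample whose recovery lay between theirs could give it too. On the first principal component replicate 3 lay at 78.25, between replicates 1 and 2 at 61.39 and 92.81. The fit therefore leaves the independence of replicate 3 in doubt in that group without deciding it. In the miR-29b and scrambled input the same fit left 0.446 and 0.531. In the scrambled pulldown it left 0.0499, where replicate 2 alone left 0.0719. An independent sample stays open in these groups too, and no biological explanation was tested.

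Between pulldowns 1 of 35 splits, the real one, gave as many as 5866 calls (highest of the other 34 splits 823). Splits need independent samples, which the fit of replicate 3 leaves in doubt in the miR-29b pulldown. They are therefore not taken to exclude chance there. For 4638 calls of the scrambled pulldown against its input (975), only the real split gave as many. Chance can be excluded there only if those libraries are independent samples that are not paired by number. The doubts about replicates 3 and 4 leave independence open. Same-number correlations of 0.314 and 0.253 in replicates 1 and 4, against 0.0564 and −0.0544 in replicates 2 and 3, leave pairing open. Numbers were taken to pair the samples between inputs and between the miR-29b pulldown and its input, by a rule that cannot establish pairs. There 8 splits part all pairs, too few for a share under 0.05. Between inputs the real one gave 7 calls and the highest other 2, and for the miR-29b pulldown against its input 6663 and 0. Over all other 34 splits the highest gave 2 and 3465. The highest other splits put the replicate 4 libraries together except between the inputs. For the 3382 calls of the mimic-specific comparison, 2 of 100 splits gave as many. These were the real one and the only other one drawn that kept the pulldown labels, which gave 4075. The splits ignored the pairs of numbers, and since each that kept the pulldown labels reached the real count, they are not taken to exclude chance here.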

How the results depend on the processing

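The subsets of replicates, the 10 libraries, the authors' totals, the other background for site marks, and the correlation of pulldown and input changes under other scalings, tools, filters, the block or only the groups compared were tests chosen only after the results were seen. Outside the settings that leave out 1 library, 5166 values of named genes kept their direction and side of the threshold, 232 lost and 131 gained a call; of list tests 1456 kept theirs, 173 lost and 47 gained a call and 4 turned. The odds ratio of site marks was 7.50 to 14.5 in these settings and 7.07 to 12.2 leaving out 1 library. Causes were not tested. For the reported targets, camera with an estimated correlation gave adjusted p = 0.48, 0.436 and 0.533 in the mimic-specific, pulldown and miR-29b pulldown against input comparisons. With a preset correlation camera gave adjusted p = 6.53e-21, 9.38e-23 and 2.16e-22 there. Between inputs camera gave the targets adjusted p = 2.53e-08 with the preset and 0.753 with the estimated correlation. The direction was upward with miR-29b (median log2 0.37), so this is no fall of target RNAs. For marked genes recovered in the miR-29b pulldown, the median log2 input ratio was 1.89 in replicate 4. In replicates 1 to 3 it was −0.19, −0.17 and −0.16. A threshold of 2-fold left 748, 1311, 1500 and 741 lower in the mimic-specific, pulldown, miR-29b pulldown against input and scrambled pulldown against input comparisons, and 4 higher between inputs and 1400 higher in the last. Upper-quartile factors gave 2400 lower (mimic-specific) and 4333 lower (pulldowns), and turned the cholesterol list in the mimic-specific comparison (fry adjusted p = 0.536) and with miR-29b against its input (0.293). In the scrambled pulldown against its input, the neural list turned with the stricter filter (fry adjusted p = 0.013) and the adipocyte list with replicates 1 to 3 (0.00246). DESeq2 called 32 higher and 14 lower between inputs. With the replicate block 1931 genes were lower in the mimic-specific comparison and 1 between inputs. In comparisons taken as paired it also ended the calls of Zmpste24 (edgeR adjusted p = 0.0543) and of the cholesterol list between inputs (fry adjusted p = 0.0582). No other call of a gene or list reported for them ended. Numbers were not taken as paired with the scrambled pulldown (lowest correlations −0.0687, −0.0544 and −0.0962), where replicate 3 correlated best with replicate 1. With only the groups compared, 0 genes were higher between inputs (edgeR) and the targets passed in the scrambled pulldown (fry adjusted p = 0.0107). Replicates 1 to 3 gave 2457 lower (mimic-specific), 82 higher and 95 lower (inputs) and 3386 lower (scrambled pulldown against input). Replicates 1, 2 and 4 gave 1004 higher and 233 lower (mimic-specific), 1463 lower (pulldowns), 0 higher (inputs), 1808 lower (miR-29b against input), and 1096 higher and 994 lower (scrambled against input). Replicates 1 and 2 gave 502 lower, 1783 lower, 0 higher (inputs), and 1530 higher and 1395 lower (scrambled). The 10 libraries gave 1273 and 180, 2086 and 955, 0 higher (inputs), 1877 lower (miR-29b against input), and 709 and 442 (scrambled). The authors' totals gave 283 lower, 1089 lower, 1 higher (inputs) and 1570 lower (miR-29b against input). The correlation of pulldown and input changes was 0.498 at 5 CPM, 0.466 with the stricter filter, 0.0275 with replicates 1 to 3, 0.0277 with 1 and 2, −0.0253 with the 10 libraries, −0.0178 with pulldown replicates 3 and 4 against input replicates 1 and 2, and 0.359 with pulldown replicates 1 and 2 against input replicates 3 and 4. Leaving out 1 library gave 783 to 1449 lower (mimic-specific), 1 to 11 higher and 0 to 2 lower (inputs), and a correlation of 0.0194 (without miR-29b input replicate 4) to 0.395. In the fractions, library totals moved the nuclear targets to 0.42 and the 8mer list to 0.85 (cytoplasm) and 0.37 (nucleus). Length-matched and region alternatives for sites, and those for normalized values, were not run.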

Other observations

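The test of the genes lowest in the mimic-specific comparison was chosen only after the result was seen. In the cytoplasmic fraction all 40 histone genes measured lay above 0 in the mimic-specific enrichment, with a median log2 value of 2.34, and all 11 snoRNA hosts did, with a median of 1.49. In the nucleus 15 of 40 histone genes and 3 of 11 snoRNA hosts lay above 0 (medians −0.14 and −0.16), and in whole cells the medians of the mimic-specific comparison were −1.25 over 51 and −0.16 over 12 genes (fry adjusted p = 0.381 and 0.839). Cell cycle genes had a cytoplasmic median of 0.80, above 99.9% of random lists, and the interferon genes one of −0.47, above 0.06% of them, against nuclear medians of 0.08 and 0.07 and whole-cell medians of −0.31 and 0.03. Between mimics the interferon genes lay below all random lists in the pulldown and in the input, at −0.91 and −0.53 in the cytoplasm and −0.31 and −0.46 in the nucleus, with 2 of 33 above 0 in the cytoplasmic input and 4 in the nuclear one. The cytoplasmic input median of the cell cycle genes was −0.13, above 0.09% of random lists. In the nucleus none of 13 mitochondrial mRNAs lay above 0 (median −0.72), while their median was 0.45 in the cytoplasm, with 9 of 13 above 0, and 0.39 in whole cells. Between the cytoplasmic inputs all 13 lay above 0 (median 0.45), and between the nuclear pulldowns none did (median −0.53). The fractions have 1 library per condition, so their values have no replicate check and their differences from whole cells were not tested.

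The genes lowest in the mimic-specific comparison may be RNAs held by the scrambled mimic itself. In the cytoplasmic fraction, whose libraries are separate, the median log2 ratio of miR-29b to scrambled pulldown over the 7 of these genes measured was −2.11, with 6 of 7 below 0. In the nuclear fraction it was −0.22. The sequence of the scrambled mimic was not used here, so pairing with these RNAs stays open.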
